A study of Homo sapiens with 6 samples.

How the data were processed

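Expression was measured by RNA sequencing in 6 libraries of A549 cells, 3 grown in AlgLung and 3 in S-AlgLung hydrogels. Per the labels' protocols, RNA was taken up in TRIzol and purified on a NucleoSpin column, and a service provider built the libraries, sequenced them and removed adaptors. Per the submitters' processing notes, the authors aligned reads with STAR 2.7.3a to GRCh38 and counted them per gene with featureCounts, whose version, annotation and strand setting are not given in the sources used here. The deposited table holds whole-number counts of reads per gene, not normalized, for 62703 genes, of which 62625 IDs matched the gene name table and 42300 had a symbol. AlgLung replicate 1 had 2 columns, with 0 genes that differed between them, and these were counted as 1 sample. Each line of the table named a gene. Among exon-overlapping gene pairs, 222 had totals within 2% of each other, 190 of them on the same strand, so the same reads appear to have been counted for more than 1 gene. Of 151 named and tested genes, 27 overlap a gene that had at least 25% of their counts, and their values are uncertain for that reason. Apart from 1 gene that is not reported here, these were PTGDS, LOXL2, ERBB3, RNF43, FAS, MUC1 and CD68 with a gene on the same strand, and INA, KRT7, KLF4, PLAU, GAS6, FGF2, IER3, BCAN, TCF7, CA9, ALDOC, ACAT2, RPL30, DDIT3, PSMB9, ICAM1, LYZ, VIM and POU5F1 with one on the other strand.

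Genes were kept with filterByExpr (minimum count 10), which left 18544. They were scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, without a block, over all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 was called. Log2 fold changes are S-AlgLung minus AlgLung, and their standard errors were approximated as the size of the log2 fold change divided by the square root of F. Values per library are TMM-scaled CPM. The biological coefficient of variation was 0.215. Total counts of 22978408 to 26495444 per library set the counting precision, and genes under about 1 CPM are the least precise. Before the data were examined, the design, the gene lists, the rule for named genes and the alternatives were fixed. In all, 38 gene lists were fixed, of which 35 had at least 5 tested members and were tested with camera in limma 3.58.1 (2-sided, preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists). Of these, 11 passed, and none of the 11 passed with a correlation estimated per list. A higher correlation did not explain every loss. The p53 target list had an estimated correlation of -0.0134, below the preset, yet its camera p went from 3.027e-06 to 0.006516. A goblet cell list, described further below, had an estimated correlation of 0.0099, close to the preset. Its camera p still went from 9.098e-06 to 0.0113. The change of setting thus raised p without a higher correlation. A list that missed the threshold under it was not thereby shown to owe its call to correlated genes.

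Named genes were the 12 with the highest and the 12 with the lowest log2 fold change among called genes with a symbol, a mean log2 CPM of at least 2 and no overlap between groups; up to 4 members with the smallest p in each list, or up to 2 in a list with none called; and 14 genes fixed by name. Alternatives were DESeq2 size factors, total counts only, upper-quartile factors, the Wald test of DESeq2 1.42.0, limma-voom, no low-count filter, a mean of at least 1 CPM, the replicate number as a block, each library left out in turn, a gene universe without mitochondrial, ribosomal protein and the 20 most abundant genes, an adjusted p under 0.01, and glmTreat against a log2 fold change of 0.5. For lists they were an estimated correlation, fry, the block, total counts and each library left out. Offsets for GC content and gene length (loess span 0.3, from transcripts of GENCODE release 29, with a GC value for 96.2% of the tested genes) were chosen after seeing the data.

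The edgeR script was tested on simulated counts for the same 18544 genes and 6 libraries, with 200 genes changed in each of 5 simulations. It recovered 6% of genes changed 1.5-fold, 48.8% of those changed 2-fold, 96.4% of those changed 4-fold and 100% of those changed 8-fold, and 4.27% of its calls were false. For DESeq2, 9.82% of calls were false. With no gene changed, edgeR called 0 genes in each of 5 simulations. The simulated genes were drawn independently and no library was set apart, unlike S-AlgLung replicate 3 in the data. These shares are therefore not error rates for the real libraries. Chi-square values per degree of freedom between libraries of the same hydrogel ran from 17.9 to 125.8, so no pair was one library deposited as a pair.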

Results

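RNA was sequenced from A549 cells, an established human lung adenocarcinoma line, grown in either of 2 hydrogels named AlgLung and S-AlgLung, with 3 libraries for each. The labels do not spell out what the S stands for; the title of the series concerns sulfation of the extracellular matrix in relation to cancer stemness and invasiveness. The deposited table holds read counts for 62703 genes. Total counts ranged from 22978408 in AlgLung replicate 2 to 26495444 in S-AlgLung replicate 2. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Libraries of the same hydrogel correlated at 0.978 to 0.989 in AlgLung and 0.971 to 0.986 in S-AlgLung (log2 CPM, counts scaled to a library total of 1e6 reads, across genes, which are not independent replicates), against 0.960 to 0.980 between hydrogels. The first principal component held 40.6% of the variance and separated the hydrogels. The second held 28.9% and set S-AlgLung replicate 3 (49.22) apart from S-AlgLung replicate 1 (-20.25) and replicate 2 (-33.36). MALAT1 and NEAT1, long noncoding RNAs retained in the nucleus, made up 0.0264% of the counts in that library and at most 0.00736% in the others.

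The comparison of S-AlgLung with AlgLung asks how gene expression in these cells differs between the 2 hydrogels. In S-AlgLung, 23 of 24 mitosis genes and 13 of 24 DNA replication genes were called lower, as were the matrix genes LAMA3 and COL5A1 and the matrix protease MMP2. Both lists missed the threshold in camera with an estimated correlation (adjusted p = 0.0783 and 0.130) and passed in all other settings. Without AlgLung replicate 2 the number of replication genes called was 4, with a median log2 fold change of -0.84 against -0.90 with all libraries. Fewer samples enter such fits, so a lost call alone does not mean a smaller fold change. Genes of mucosal secretion (MUC16, TFF3, BPIFB2 and REG4) and the immediate early genes JUN, FOS and EGR1 were higher. Of 18544 genes tested with edgeR, 584 were higher and 369 lower in S-AlgLung at an adjusted p under 0.05, and 442 and 296 of these differed at least 2-fold. In 18.5% of all tested genes the 3 values of one hydrogel did not overlap those of the other, against 10% by chance for 3 against 3. Scaling by total counts alone gave 333 higher and 335 lower genes and moved the median of all genes by -0.10 (log2), so the excess of higher over lower genes depended on the scaling. Without S-AlgLung replicate 3 there were 891 higher and 662 lower genes; without AlgLung replicates 1, 2 and 3 in turn there were 289, 307 and 326 higher genes, and without AlgLung replicate 2 there were 244 lower ones.

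The 12 called genes with the highest fold changes included several made by secretory and mucosal epithelium. DUOX2, a hydrogen peroxide-producing oxidase (chromosome 15, 45092650 to 45114172, GRCh38), rose 20.4-fold, from 0.733 ± 0.290 to 15.2 ± 4.20 CPM (mean ± SD, n = 3), a log2 fold change of 4.35 (SE 0.32, adjusted p = 4.454e-10). BPIFB2 (chromosome 20, 33007704 to 33023703) rose 12.5-fold, from 3.04 ± 1.34 to 37.9 ± 9.89 CPM. The mucin gene MUC16 (chromosome 19, 8848844 to 8981342) rose from 4.43 ± 0.681 to 51.3 ± 20.9 CPM (adjusted p = 9.897e-10). TFF3, a trefoil peptide secreted with mucus, rose from 8.72 ± 1.09 to 81.0 ± 27.2 CPM and REG4, a secreted lectin, from 16.4 ± 6.79 to 135.5 ± 38.2 CPM. DEPP1, DCDC1, SUCNR1 (a succinate receptor) and SERPINA1 (alpha-1 antitrypsin) rose 9.73-fold, 6.02-fold, 5.92-fold and 5.55-fold. The transcription factor genes ATF3 and JUN rose 8.97-fold and 6.65-fold. Both were highest in S-AlgLung replicate 3, at 56.6 CPM for ATF3 and 297 CPM for JUN, against 9.88 and 16.4 CPM and 93.6 and 113.8 CPM in the other 2 S-AlgLung libraries. Without that library both were still called, at 4.18-fold for ATF3 and 4.02-fold for JUN. PTGDS, prostaglandin D2 synthase, rose from 4.19 ± 0.951 to 48.1 ± 5.41 CPM, but nearly the same number of reads was counted for the overlapping gene ENSG00000284341 on the same strand, so its reads cannot be assigned to one gene.

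**Figure D1:**
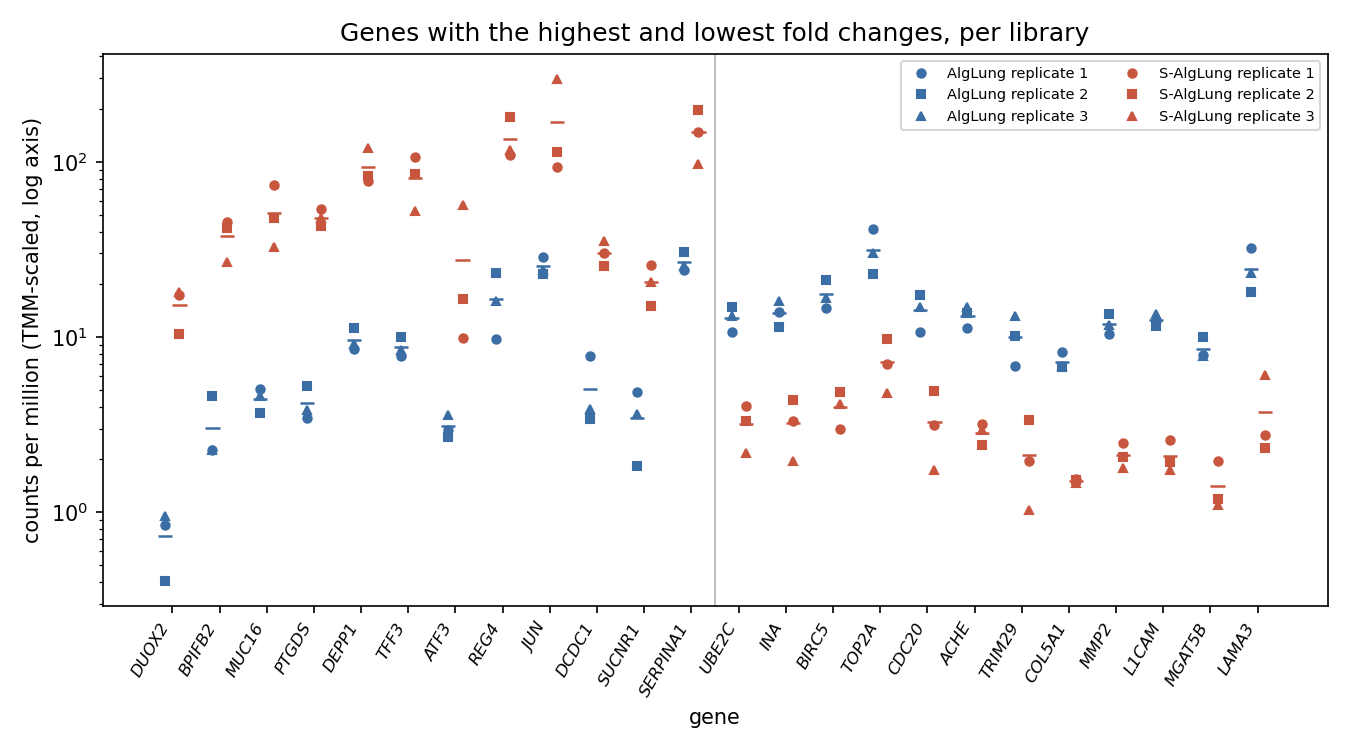
TMM-scaled CPM (log axis) of the 12 genes with the highest and the 12 with the lowest fold changes in each of the 6 libraries; each point is a library, blue for AlgLung and red for S-AlgLung, and horizontal bars mark the mean of 3. The rule that chose these 24 genes required groups without overlap, and ATF3 ranged from 9.88 to 56.6 CPM within S-AlgLung.

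Among the 12 genes with the lowest fold changes were matrix, adhesion and cell division genes. LAMA3, a laminin chain of epithelial basement membranes (chromosome 18, 23689453 to 23956222), fell from 24.6 ± 7.24 to 3.72 ± 2.05 CPM (mean ± SD, n = 3), a log2 fold change of -2.71 (SE 0.30, adjusted p = 7.902e-07), and -3.30 without S-AlgLung replicate 3. MGAT5B, a glycosyltransferase gene, fell from 8.55 ± 1.28 to 1.41 ± 0.468 CPM. The cell adhesion gene L1CAM (chromosome X, 153861514 to 153886173) fell from 12.5 ± 0.998 to 2.09 ± 0.440 CPM (log2 fold change -2.59, SE 0.26), and MMP2 (chromosome 16, 55389700 to 55506691), a gelatinase, from 11.8 ± 1.58 to 2.11 ± 0.361 CPM (log2 fold change -2.49, SE 0.26). COL5A1, a fibrillar collagen chain, fell by 2.26 on the log2 scale and TRIM29 by 2.25. ACHE, the acetylcholinesterase gene, fell by 2.21. CDC20, TOP2A, BIRC5 and UBE2C, which act in mitosis, fell by 2.15, 2.13, 2.13 and 2.03. INA, an intermediate filament gene, fell by 2.10, but its exons overlap NT5C2 on the other strand, which had 9.90 times its counts, and the strand setting of the counting is not given in the sources used here.

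Most mitosis genes were called lower, and the list passed as a whole in all settings except camera with an estimated correlation. Of 24 mitosis and G2/M genes, 23 fell, and 24 when adjusted over the list alone. The median log2 fold change was -1.83, and the list ranked below other genes (camera adjusted p = 1.469e-56; adjusted p = 0.0783 with an estimated correlation, which missed the threshold). Camera also gave this list adjusted p as low as 2.411e-19 in groupings of the 6 libraries that mix the hydrogels, where no gene was called; each such grouping sets 2 libraries of a hydrogel against 1, so part of the difference between hydrogels remains in it. DLGAP5, a spindle assembly gene, fell by 2.87 on the log2 scale, and MKI67, the gene of the proliferation marker Ki-67, fell from 29.3 ± 7.46 to 8.08 ± 3.72 CPM (log2 fold change -1.86, SE 0.27, adjusted p = 3.917e-05). Of 24 DNA replication and G1/S genes, 13 fell, and 15 when adjusted over the list alone, with a median of -0.90 (camera adjusted p = 5.741e-17; adjusted p = 0.130 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 1.71, the replication licensing gene CDC6 by 1.92, E2F1 by 1.49 and MCM4 by 1.16. Without AlgLung replicate 2 the number of these genes called was 4, and without S-AlgLung replicate 1 it was 7. The medians in these fits were -0.84 and -0.83. Of 31 replication-dependent histone genes, 11 had enough counts to test, and none was called (camera adjusted p = 0.198). H3C10 was at -0.60 (2.48 CPM in AlgLung and 1.62 in S-AlgLung). H2BC4 was at -0.63 (1.67 and 1.08 CPM). At such low levels the lack of calls says little. Of 25 p53 target genes, 6 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone (median -0.40, camera adjusted p = 3.532e-05; adjusted p = 0.114 with an estimated correlation). Without AlgLung replicate 1 the number of p53 targets called lower was 3. SPATA18 fell from 3.56 ± 0.325 to 0.762 ± 0.167 CPM. FAS, which shares a strand and exons with STAMBPL1, fell by 1.57 and CDKN1A, an inhibitor of cyclin-dependent kinases, by 1.09, whereas GDF15 was higher by 0.86. The CDKN1A call was lost without AlgLung replicate 2 (adjusted p = 0.0635), and that of GDF15 without AlgLung replicates 1, 2 and 3 (adjusted p = 0.203, 0.102 and 0.149) and with total-count scaling (0.0663) or GC and length offsets (0.0745).

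Genes of matrix structure and invasion changed in both directions. Of 27 collagen and basement membrane genes, 5 fell and 1 rose, and 7 fell and 3 rose when adjusted over the list alone (median -0.19, camera adjusted p = 0.00160; adjusted p = 0.587 with an estimated correlation). Beside LAMA3 and COL5A1, the microfibril gene FBN1 fell by 1.57 and COL6A2 by 0.98. The number called higher was 0 without AlgLung replicates 1, 2 or 3 and 2 without S-AlgLung replicate 3. Of 21 matrix proteases and inhibitors, 4 fell and 1 rose, the same numbers as when adjusted over the list alone (camera adjusted p = 0.0722). PLAT, tissue plasminogen activator, fell by 2.39 and PLAU, urokinase, by 0.89, and MMP14, a membrane-bound protease, was higher by 1.03. The number called lower was 2 without AlgLung replicate 2, S-AlgLung replicate 1 or S-AlgLung replicate 2, and 2 were called higher without S-AlgLung replicate 2 or 3. The list passed the threshold as lower without AlgLung replicate 1 (adjusted p = 0.0379), without S-AlgLung replicate 1 (0.0172) and with GC and length offsets (0.0287). The PLAU call was lost without AlgLung replicate 2 (adjusted p = 0.0716), S-AlgLung replicate 1 (0.0761) or S-AlgLung replicate 2 (0.0868). That of MMP14 was lost without AlgLung replicates 1, 2 and 3 (adjusted p = 0.221, 0.0953 and 0.0876) or S-AlgLung replicate 1 (0.0690). It was also lost with total-count scaling (0.145) and with GC and length offsets (0.0529). The log2 fold change of MMP14 was 0.82, 1.07 and 1.11 without AlgLung replicates 1, 2 and 3 and 1.08 without S-AlgLung replicate 1. Of 27 integrin and focal adhesion genes, 2 fell and 1 rose, as when adjusted over the list alone (camera adjusted p = 0.0490; adjusted p = 0.587 with an estimated correlation). The list's call was lost without AlgLung replicate 1 (adjusted p = 0.0526), AlgLung replicate 3 (0.0727) or S-AlgLung replicate 3 (0.264). Without AlgLung replicate 1 or 3 the number called lower was 1. ITGB8 fell by 1.35, whereas the actin-linking adhesion gene TNS1 rose by 1.01, a call lost without AlgLung replicate 3 (adjusted p = 0.0950). Of 15 proteoglycan core protein genes only SPOCK1 was called, also when adjusted over the list alone, and it rose by 2.02 (camera adjusted p = 0.473). HSPG2, the gene of perlecan, was at 0.59 (adjusted p = 0.323), and without S-AlgLung replicate 3 it was called higher at 0.84 (adjusted p = 0.00699). None of 29 genes of sulfated glycosaminoglycan synthesis was called (camera adjusted p = 0.858), with UST at -1.18 (SE 0.51, adjusted p = 0.248) and EXTL2 at -0.61 (SE 0.27, adjusted p = 0.262). Without S-AlgLung replicate 3 both were called lower, UST at -1.81 and EXTL2 at -0.86 (adjusted p = 0.0351 and 0.0205). UST was under 1 CPM in both hydrogels (0.756 in AlgLung and 0.326 in S-AlgLung), with 81 counts in all 6 libraries.

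The lists that bear on stemness and on epithelial or mesenchymal state did not pass as groups. Of 19 stemness-associated genes, 1 rose and 2 fell, and 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.213). Without S-AlgLung replicate 2 the number called higher was 2, and without AlgLung replicate 1 or 3 or S-AlgLung replicate 1 the number called lower was 1. LGR6, an R-spondin receptor, fell by 2.01, and HES1, a Notch target, rose by 1.31. ABCG2, a drug efflux transporter, was lower by 0.88, a call lost without AlgLung replicate 1 (adjusted p = 0.0530), AlgLung replicate 3 (0.0815) or S-AlgLung replicate 1 (0.0736). KLF4, with overlapping groups, was at 0.92 (adjusted p = 0.0701). It was called higher with upper-quartile factors (adjusted p = 0.0427), without a low-count filter (0.00877) and without S-AlgLung replicate 2 (0.00179). SOX2 was at 0.21 (SE 0.23, adjusted p = 0.781) and CD44 at 0.16 (SE 0.25, adjusted p = 0.866). POU5F1 was near 1 CPM in both hydrogels, at 0.665 ± 0.359 and 0.857 ± 0.593. NANOG had 0 counts and SNAI2 had 15 counts in all 6 libraries, too few to test. Of 21 mesenchymal genes, 2 rose and 4 fell, and 2 rose and 5 fell when adjusted over the list alone (median -0.06, and 0.06 without AlgLung replicate 2; camera adjusted p = 0.0575). The list passed the threshold as lower without AlgLung replicate 1 (adjusted p = 0.0381), without S-AlgLung replicate 2 (0.0394), with total-count scaling (0.0464), with GC and length offsets (0.0192) and with fry (0.0146). The number called lower was 2 without AlgLung replicate 2 or S-AlgLung replicate 1. MMP2 and LOXL2, a collagen cross-linking enzyme, fell by 2.49 and 1.22 (LOXL2 shares a strand and exons with ENTPD4), whereas SNAI1, a repressor of epithelial genes, rose 5.23-fold, from 0.947 ± 0.241 to 4.94 ± 1.02 CPM, and TNC, tenascin C, rose 3.01-fold. CDH1 (0.33, SE 0.23), VIM (0.10, SE 0.26), CDH2 (0.14, SE 0.21) and ZEB1 (-0.33, SE 0.24) differed by less than the test could call (adjusted p of 0.564 to 0.933). Of 21 epithelial junction and keratin genes, 2 rose and 1 fell, and 3 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.566). The number called higher was 1 without AlgLung replicate 1 or 2 and 0 without AlgLung replicate 3. KRT7 fell by 1.44, and CLDN4, a tight junction gene, was higher by 0.99, a call lost without AlgLung replicate 1 (adjusted p = 0.112) or 3 (0.0554). Of 12 lung epithelial lineage genes, 1 rose and 1 fell, as when adjusted over the list alone (median 0.38, camera adjusted p = 0.171). Without S-AlgLung replicate 3 the list passed the threshold (adjusted p = 0.0102) and 3 genes were called higher. MUC5B was at 5162 ± 1349 CPM in AlgLung and 12910 ± 7170 in S-AlgLung (adjusted p = 0.0254), with overlapping groups, and its call was lost without S-AlgLung replicate 1 (adjusted p = 0.322) or any AlgLung replicate (0.0692, 0.171 and 0.237), with DESeq2 size factors (0.0531) and with limma-voom (0.0735). TP63, a basal cell factor, was lower by 0.87, a call lost without AlgLung replicate 3 (adjusted p = 0.0890) or S-AlgLung replicate 2 (0.0524).

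**Figure D2:**
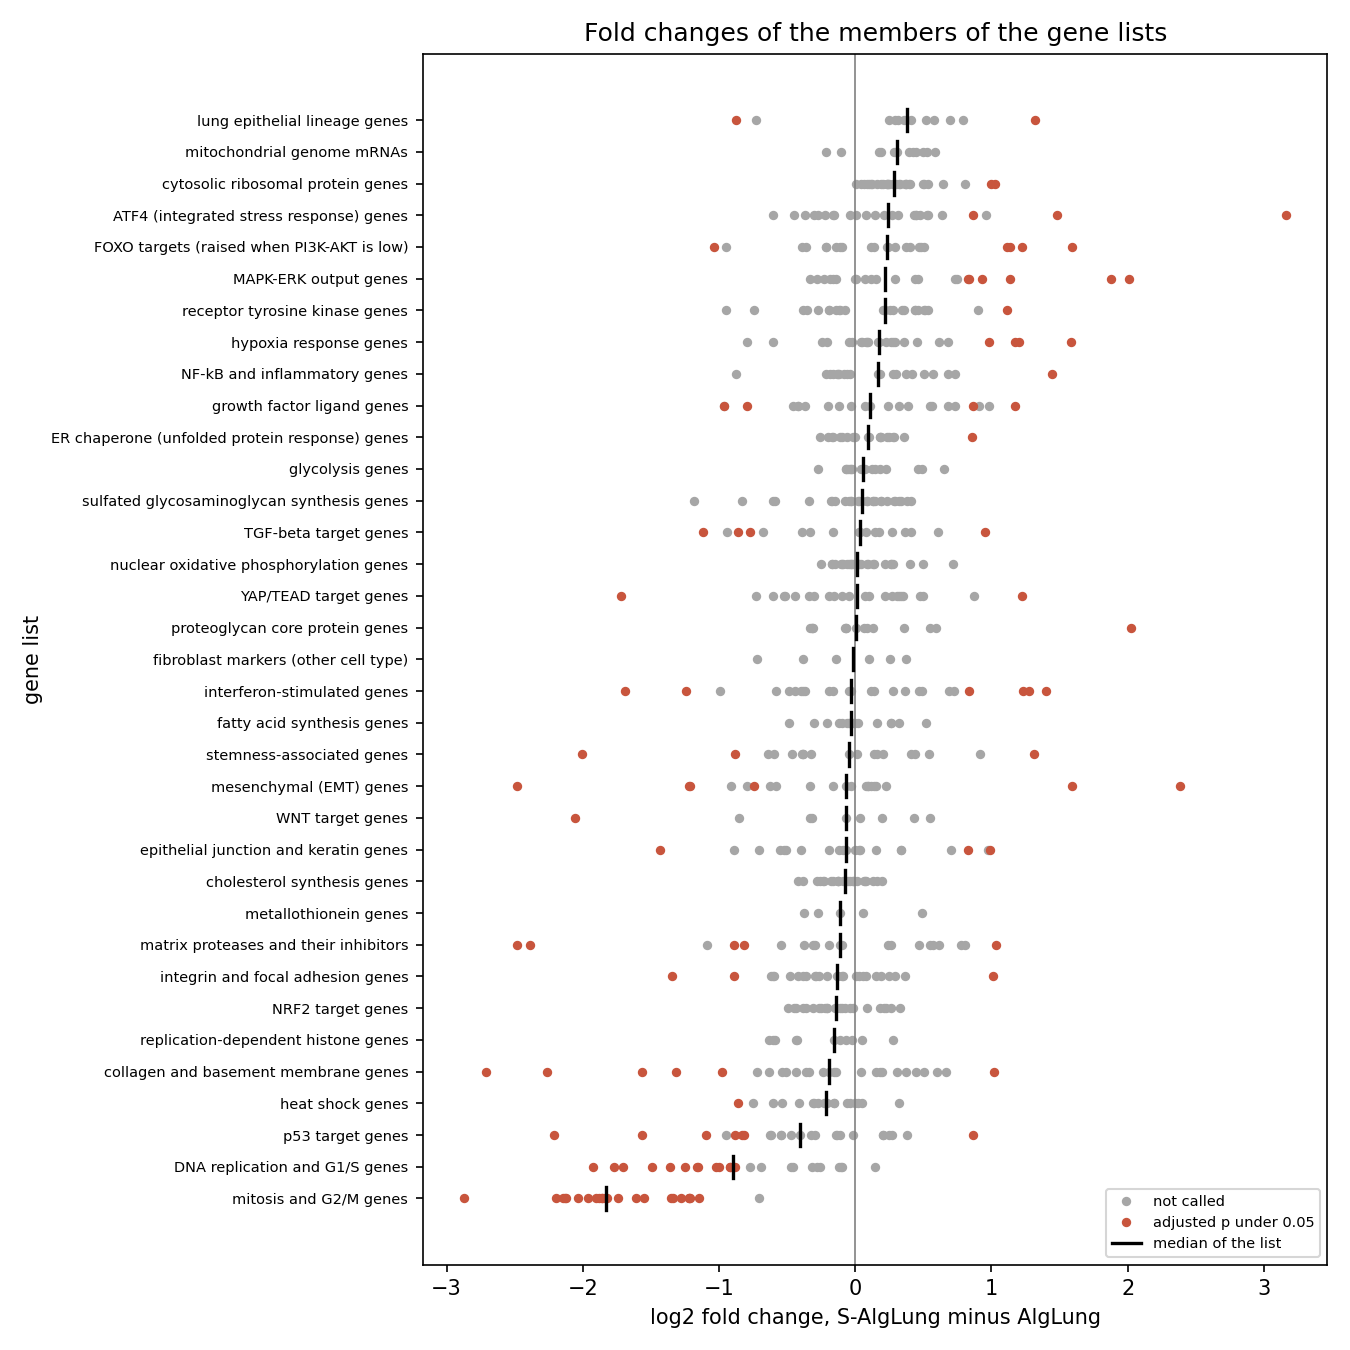
Log2 fold change (S-AlgLung minus AlgLung) of each tested member of the 35 gene lists with at least 5 tested members; red points have an adjusted p under 0.05, grey points do not, and black bars are list medians. The mitosis and G2/M list has the lowest median, -1.83, followed by the DNA replication and G1/S list at -0.90.

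Among growth factor receptors, ERBB3 was the only called gene of 25 receptor tyrosine kinases, also when adjusted over the list alone, at 29.5 ± 3.61 CPM in AlgLung and 64.0 ± 5.20 in S-AlgLung (log2 fold change 1.12, SE 0.22, adjusted p = 0.00116). A gene without a symbol that overlaps ERBB3 on the same strand had 1.75 times its counts. EGFR (-0.36), MET (-0.27) and AXL (0.22) had adjusted p of 0.540, 0.702 and 0.764, and the list did not pass (camera adjusted p = 0.380). Without S-AlgLung replicate 2 or 3, 2 receptor genes were called higher. FGFR4, at -0.74 (adjusted p = 0.131), was called lower with total-count scaling (0.0440) and with GC and length offsets (0.0218), and FGFR3, at 0.90 (0.0809), was called higher without a low-count filter (0.0467) and without S-AlgLung replicate 2 (0.0244). PTK2, the gene of focal adhesion kinase, was at 0.01 (SE 0.23, adjusted p = 0.996). Of 23 growth factor ligand genes, 2 rose and 2 fell, and 4 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.501). The number called higher was 1 without AlgLung replicate 1 or 3. The number called lower was 1 without any AlgLung replicate or S-AlgLung replicate 2, and 4 without S-AlgLung replicate 3. VEGFA rose by 1.17, with 85.7 CPM in S-AlgLung replicate 3 against 52.9 and 44.2 CPM in the other S-AlgLung libraries, and GAS6 was lower by 0.96, the latter not without AlgLung replicate 2 (adjusted p = 0.0602). Of 22 MAPK-ERK output genes, 6 rose, and 7 when adjusted over the list alone (median 0.22, camera adjusted p = 0.00179; adjusted p = 0.587 with an estimated correlation). The number called was 3 without AlgLung replicate 1, AlgLung replicate 3 or S-AlgLung replicate 1. FOS rose 3.67-fold and EGR1 4.02-fold. Both were highest in S-AlgLung replicate 3, where FOS was at 133.8 CPM against 60.8 and 64.2 CPM in the other S-AlgLung libraries. The MAPK phosphatase gene DUSP5 rose by 1.14. Of 23 FOXO targets, which are raised when PI3K-AKT signalling is low, 4 rose and 1 fell, and 4 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.144). The list passed without AlgLung replicate 1 (adjusted p = 0.0408) or S-AlgLung replicate 2 (0.0275) and with GC and length offsets (0.0489). Without AlgLung replicate 2 the number called higher was 2, and without S-AlgLung replicate 3 the number called lower was 2. TXNIP rose by 1.59 and PDK4 fell by 1.03. Of 18 TGF-beta targets, 1 rose and 3 fell (camera adjusted p = 0.198), with ID3 fallen by 1.12. The number called lower was 1 without AlgLung replicate 2 or 3 or S-AlgLung replicate 2, and 5 without S-AlgLung replicate 3, and the number called higher was 0 without any AlgLung replicate. Of 24 YAP/TEAD targets, 1 rose and 1 fell (adjusted p = 0.608), with FJX1 fallen by 1.72 and GADD45B risen by 1.22, and 2 were called higher without S-AlgLung replicate 2. Of 9 WNT targets, NKD1 was the only one called, at 0.639 ± 0.211 CPM in AlgLung and 0.157 ± 0.104 in S-AlgLung, and DESeq2 did not call it (adjusted p = 0.124; camera adjusted p of the list, 0.475). Its call was lost also without AlgLung replicates 1 and 2 and S-AlgLung replicates 2 and 3 (adjusted p = 0.201, 0.0960, 0.0716 and 0.0699), and its log2 fold change of -2.06 was -2.67 without S-AlgLung replicate 1. Adjusted over the list alone, 1 TGF-beta target rose and 5 fell, 2 YAP/TEAD targets rose and 1 fell, and 1 WNT target fell.

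Of 25 hypoxia response genes, 4 rose, and 5 when adjusted over the list alone (median 0.17, camera adjusted p = 0.0215; adjusted p = 0.587 with an estimated correlation). The list's call was lost without AlgLung replicate 3 (adjusted p = 0.0533) or S-AlgLung replicate 3 (0.204), and without the latter the median was -0.01. ADM, VEGFA and EGLN3 were highest in S-AlgLung replicate 3, at 107.1, 85.7 and 289.9 CPM, and CA9 was lowest there among the S-AlgLung libraries, at 348.9 CPM. CA9, a carbonic anhydrase whose exons overlap ARHGEF39 on the other strand, rose from 134.8 ± 19.4 to 403.7 ± 48.5 CPM and ADM, adrenomedullin, from 40.6 ± 4.30 to 93.1 ± 12.2 CPM. Of 26 ATF4 genes, 3 rose, and 4 when adjusted over the list alone (median 0.24, camera adjusted p = 0.0490; adjusted p = 0.587 with an estimated correlation). ATF3, which was highest in S-AlgLung replicate 3, led this list, and STC2 rose by 1.48. The ATF4 list lost its call without AlgLung replicate 1 (adjusted p = 0.180), AlgLung replicate 2 (0.0762) or S-AlgLung replicate 2 (0.128) and with total-count scaling (0.0736) or GC and length offsets (0.145). Of 30 cytosolic ribosomal protein genes, 2 rose, as when adjusted over the list alone (median 0.29, camera adjusted p = 0.00640; adjusted p = 0.587 with an estimated correlation), and the list's call was lost without AlgLung replicate 1 (adjusted p = 0.110). RPS24 and RPS27 were highest in S-AlgLung replicate 3, at 514.5 and 563.1 CPM. Without that library the adjusted p of RPS24 was 0.153, and without AlgLung replicates 1, 2 and 3 it was 0.141, 0.188 and 0.242; for RPS27 it was 0.337, 0.0988 and 0.156 without the AlgLung replicates. Neither was called with DESeq2 size factors (adjusted p = 0.0523 and 0.0581), total-count scaling (0.0688 and 0.0522) or limma-voom (0.0692 and 0.0673), nor RPS27 with GC and length offsets (0.0659). Of 18 heat shock genes, 1 was lower, as when adjusted over the list alone (median -0.22, camera adjusted p = 0.0223; adjusted p = 0.587 with an estimated correlation). The heat shock list lost its call without AlgLung replicate 3 (adjusted p = 0.0533), S-AlgLung replicate 1 (0.102) or S-AlgLung replicate 3 (0.0785). HSP90AA1, at -0.75 (adjusted p = 0.153), was called lower with total-count scaling (0.0355) and without S-AlgLung replicate 2 (0.0331). The gene called in the main test, CHORDC1, was lower by 0.86. Without AlgLung replicates 1 and 3 and S-AlgLung replicate 2 its adjusted p was 0.0756, 0.0676 and 0.0522. None of the 13 mitochondrial genome mRNAs was called, although the list passed (median 0.31, camera adjusted p = 0.0490; adjusted p = 0.733 with an estimated correlation). That call was lost without any of AlgLung replicates 2 and 3 and S-AlgLung replicates 1 and 2 (adjusted p = 0.291, 0.273, 0.321 and 0.0630). MT-ND2 was at 0.58 and MT-ND1 at 0.50.

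Of 25 interferon-stimulated genes, 4 rose and 2 fell, and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.535). Without AlgLung replicate 1 or 2 the numbers were 2 higher and 0 lower, and without AlgLung replicate 3 or S-AlgLung replicates 1 or 2, 1 was called lower. HLA-B, PSMB9 and B2M, which act in class I antigen presentation, were higher by 1.23, 1.40 and 1.28, and the antiviral gene ISG15 was lower by 1.24. PSMB9 overlaps PSMB8 on the other strand, which had 3.34 times its counts. The B2M and ISG15 calls were lost without AlgLung replicate 1 (adjusted p = 0.123 and 0.198) or 2 (0.0586 and 0.0727). Their log2 fold changes were 1.02 and -1.03 without AlgLung replicate 1, and 1.40 and -1.42 without AlgLung replicate 2. Of 21 NF-kB and inflammatory genes, only CCL2, a chemokine, was called, higher by 1.44 (camera adjusted p = 0.411), and 2 rose and 1 fell when adjusted over the list alone. Without S-AlgLung replicate 2 or 3, 2 were called higher and 1 lower, and without AlgLung replicate 3, 1 was called lower. LCN2, lipocalin 2, was at -0.88 (adjusted p = 0.0555) and was called lower with limma-voom (adjusted p = 0.0443), total-count scaling (0.0359), upper-quartile factors (0.0166) and no low-count filter (0.00606), and without AlgLung replicate 3 (0.0451) or S-AlgLung replicate 2 (0.00179). Of 20 ER chaperone and unfolded protein response genes, XBP1 was the only one called, also when adjusted over the list alone. It was higher by 0.86 with an adjusted p of 0.0454 (camera adjusted p of the list, 0.576). XBP1 was not called by limma-voom (adjusted p = 0.0551) or with DESeq2 size factors (0.0675) or total-count scaling (0.0582). Its call was also lost without any of the 6 libraries except S-AlgLung replicate 3 (adjusted p of 0.0553 to 0.334). No gene was called in edgeR, DESeq2 or limma-voom in 11 lists with 177 tested genes, of which 9 had an unadjusted p under 0.05 in edgeR. Beside the histone, glycosaminoglycan synthesis and mitochondrial genome lists, these were glycolysis (16 genes, camera adjusted p = 0.608; ALDOC at 0.65, ENO2 at 0.49), cholesterol synthesis (25 genes, 0.257; ACAT2 at -0.42, LSS at -0.38) and fatty acid synthesis (16 genes, 0.827; ELOVL5 at 0.52, ACSL3 at -0.49). They also included nuclear oxidative phosphorylation (29 genes, 0.841; COX7C at 0.71; 1 gene called lower without S-AlgLung replicate 3), NRF2 targets (24 genes, 0.172; GCLM at -0.43) and metallothioneins (5 genes, 0.640; MT1A at 0.49). ALDOC was called without S-AlgLung replicate 3 (adjusted p = 0.00495), and the NRF2 list passed as lower without S-AlgLung replicate 2 (adjusted p = 0.0275). Fibroblast markers (6 genes, 0.608; FBLN1 at -0.72) and endothelial markers (3 genes; PECAM1 at 0.79) were the other 2. EGFL7, an endothelial marker, was at 0.56 and was called without S-AlgLung replicate 3 (adjusted p = 0.00134), and FBLN1 was called without S-AlgLung replicate 2 (adjusted p = 0.0481), with upper-quartile factors (0.0420), without a low-count filter (0.0435) and with GC and length offsets (0.0166). Adjusted over the list alone, 1 fibroblast marker fell and none of the other 10 lists had a called gene. Of 4 tested leukocyte markers, CD68 (81.6 ± 20.6 and 160.5 ± 15.1 CPM) and CD14 (32.8 ± 4.14 and 59.1 ± 14.3 CPM) were called, and neither was called without any of AlgLung replicates 1, 2 and 3 (adjusted p = 0.236, 0.0599 and 0.0771 for CD68; 0.192, 0.0700 and 0.246 for CD14) or without S-AlgLung replicate 1 (adjusted p = 0.0617 and 0.101). CD14 was also not called without S-AlgLung replicate 2 (adjusted p = 0.0961) or with total-count scaling (0.0744). Adjusted over the list alone, 3 leukocyte markers were called higher. None of the fixed erythroid markers had enough counts to test. Median and mean differed in sign for the glycosaminoglycan synthesis, TGF-beta, YAP/TEAD, interferon and fatty acid lists.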

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

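The offsets for GC content and gene length were the only alternative chosen after the data were seen. Of the 953 called genes, 0 changed sign among those that each refit tested, and some refits tested fewer genes. With GC and length offsets 795 of the 953 stayed called. The number was 830 with the DESeq2 Wald test, 835 with limma-voom and 928 with upper-quartile factors. Across genes, log2 fold change correlated with GC content (Spearman rho 0.234) and with gene length (-0.102). Against 584 higher and 369 lower genes, the counts stayed within 1.5 times for DESeq2 size factors, upper-quartile factors, the DESeq2 Wald test, limma-voom, both other filters, the universe without abundant genes and the GC and length offsets, over a range of 495 to 719 higher and 308 to 430 lower. Scaling by total counts only gave 333 higher genes, 294 of them at least 2-fold; its own construction leaves out composition, and 49.9% of its calls were higher against 61.3%. An adjusted p under 0.01 gave 323 higher and 217 lower genes and glmTreat 264 and 188, as stricter thresholds do. With 1 library left out, the counts ranged from 289 to 891 higher, 244 to 662 lower and, at least 2-fold, 276 to 564 higher; fewer samples enter these fits, and why leaving out S-AlgLung replicate 3 raised the count was not tested.

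The replicate numbers did not clearly mark shared deviations. Same-numbered libraries correlated at 0.072, 0.285 and 0.041, and the other pairs at -0.338 to 0.208. Not every library correlated best with its own number. With 3 libraries per hydrogel, a pairing cannot be excluded. The replicate block gave 800 higher and 500 lower genes, with 463 and 318 at least 2-fold, and 11 lists, as without it.

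Of the gene lists, 11 passed with the preset correlation, 0 with an estimated one, 4 with fry, which does not compare a list with other genes, and 7 to 12 with 1 library left out. The mitosis list had an adjusted p = 0.0783 and the DNA replication list an adjusted p = 0.130 with an estimated correlation, and both passed in all other settings. The mesenchymal list passed as lower with fry (0.0146), total counts (0.0464) and the GC and length offsets (0.0192), and ranged from 0.0381 to 0.161 with 1 library left out. The protease list passed with the GC and length offsets (0.0287) and ranged from 0.0172 to 0.176 with 1 library left out. The stemness list passed in no setting. The causes of these list changes were not tested. Depth limits genes near 1 CPM, such as POU5F1 and NKD1.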

Other observations

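Leaving out each library in turn was a fixed alternative. Its use to test S-AlgLung replicate 3 as an explanation, and the test of p53 targets, were chosen after the result was seen. The GC and length test, the nuclear RNA test, the goblet cell test and the splits were set out before their results were seen.

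Mucus and goblet cell genes outside the fixed lists were also examined, after MUC16, TFF3, BPIFB2 and REG4 had been seen among the highest fold changes. A list of 36 goblet and mucous cell genes was written without these 4, and 24 of its genes were tested. TSPAN8 (log2 fold change 1.24, SE 0.23), CEACAM6 (1.33, SE 0.27), AGR3 (1.61, SE 0.35), BPIFA1 (1.33, SE 0.32) and TSPAN1 (0.86, SE 0.26) were called higher and 0 lower. CEACAM6, an adhesion protein of mucosal epithelium, was at 885.9 CPM in AlgLung and 2220 CPM in S-AlgLung. AGR2 (-0.02), FCGBP (0.01), SLPI (0.04) and GCNT3 (0.07), also in the list, were not called. The median was 0.42 and the list ranked above other genes (camera p = 9.098e-06; p = 0.0113 with an estimated correlation; p = 7.845e-07 without S-AlgLung replicate 3). As a hypothesis, S-AlgLung may raise part of a mucous secretory programme; the list was built after related genes had been seen, and its abundant members AGR2 and FCGBP were near 0. Of the abundant secreted mucins, MUC5B was called higher (log2 fold change 1.32, edgeR adjusted p = 0.0254) and MUC5AC was not (4663 ± 1738 CPM in AlgLung and 8049 ± 4372 in S-AlgLung, SD, n = 3; adjusted p = 0.284, and 0.00520 without S-AlgLung replicate 3), and the groups overlapped for both. Together they took 3.03%, 1.74% and 1.12% of the counts in S-AlgLung replicates 1, 2 and 3 and 1.42%, 0.961% and 0.699% in AlgLung replicates 1, 2 and 3.

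The fall of mitosis and G2/M genes was weighed against 3 explanations. A single deviating library would have left little of it, yet without S-AlgLung replicate 3 the median was -1.63 and 23 members were still called lower. With each library left out in turn, 19 to 23 members were called lower and the median ran from -1.88 to -1.56. With offsets for GC content and gene length the median was -1.67 and 20 members were called, so those trends do not account for the whole fall. Activation of p53 in S-AlgLung, which represses such genes, would raise its targets, but their median was -0.40. The SE of their mean was 0.13, over genes, which are not independent replicates. CDKN1A was called lower, a call lost without AlgLung replicate 2 (adjusted p = 0.0635). A smaller share of dividing cells in S-AlgLung, as a hypothesis, may underlie the fall; cell numbers and time of culture were not analysed here, so this biological explanation and others tied to the hydrogel remain untested.

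Of 8 immediate early genes and relatives, all but IER3 were highest in S-AlgLung replicate 3. The 8 were picked after the result was seen, and all were called with all libraries (edgeR adjusted p of 1.811e-06 to 0.0331). If that library alone carried the difference, the calls would be lost without it, yet 8 of the 8 genes ATF3, JUN, SOCS3, DUSP1, EGR1, FOS, IER3 and JUNB were still called higher, with log2 fold changes of 2.06 for ATF3 (SE 0.24) against 3.16 with all libraries, and 2.01 for JUN (SE 0.21) against 2.73. The library thus set part of the size of the fold changes but not these calls. Leaving it out also lowered the SE of ATF3 from 0.40 to 0.24, which makes a call easier to keep. IER3 was not called without AlgLung replicate 1 (adjusted p = 0.162), AlgLung replicate 3 (0.255) or S-AlgLung replicate 1 (0.0554), nor JUNB without AlgLung replicates 1, 2 and 3 (0.199, 0.0832 and 0.465) or S-AlgLung replicates 1 and 2 (0.0617 and 0.0820). Handling of the cells before lysis can also induce these genes and was not tested, since no label records it; an effect of the hydrogel also stays open.

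S-AlgLung replicate 3 also held more nuclear RNA: MALAT1 was 2.24 (log2) above the mean of the other S-AlgLung libraries, and NEAT1 was raised with it. A larger nuclear share of the RNA as the whole cause would raise other nuclear long noncoding RNAs by at least 1, but the median of 18 such RNAs was 0.55 (SE of the mean 0.14). All 18 lay above 0, against 55.3% of all tested genes and a median of 0.07 over these. That comparison was not matched for abundance or for noncoding genes. The library also had the most genes with at least 10 counts, 19437 against at most 18614 in the others. A nuclear excess may contribute, but the 18 RNAs do not single it out, and no biological explanation was tested. NORAD, in that list, is largely cytoplasmic, and the median without it was 0.56.

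Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 953 genes in edgeR, 738 of them at least 2-fold, and the highest of the other 9 called 0 and 0; 1 split in each case, the real one, reached the count. Unadjusted p under 0.05 were found for 2765 genes in the real split and for 210 to 2875 in the others, which were run in edgeR alone. For lists called by camera the real split gave 11 and the highest other split 14, and 4 of the 10 splits gave 11 or more. In the other splits the mitosis list reached an adjusted p as low as 2.411e-19 with 0 genes called. Each of these splits sets 2 libraries of a hydrogel against 1 and so keeps part of the difference between hydrogels, and such a p is no value for no difference.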
